A study of Drosophila melanogaster with 7 samples.

How the data were processed

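RNA bound to Piwi was measured by RNA immunoprecipitation and sequencing (RIP-seq) in OSC cells, a line of Drosophila ovarian somatic cells. Per the labels' protocols, extracts were kept with anti-Piwi antibody on beads for 3 h, and the mock precipitation had no antibody. One culture was treated with actinomycin D (ActD), a drug that blocks transcription, at 1 µg/ml for 1 h. The precipitated RNA was fragmented, primed with random hexamers and sequenced as 51-nt single-end reads, per the labels' protocols. The 3 RIP libraries (mock, untreated Piwi RIP and ActD Piwi RIP) were 1 per group. The 4 DamID samples of the series were not analysed here.

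Each deposited file lists distinct read sequences, each with its count of reads, and holds no alignment. The authors had collapsed identical reads, since each sequence stands once per file. The sequences are 18 to 50 nt long, so at least 1 base had been removed from each read. The trimming tool is not given in the sources used here. The submitters' processing notes name TopHat and the dm3 build, but no reference genome or annotation was used here, and no coordinate or gene name is given. Totals were 18880147 reads for the mock, 18054986 for the untreated Piwi RIP and 18875500 for the ActD Piwi RIP.

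The labels' protocols do not say that the libraries keep the strand. The strand was taken from the data: all reads were reverse-complemented, and this orientation is called the RNA strand, so antisense reads are antisense to it. The reads were pooled over the libraries without regard to group, and assembled with a greedy strand-specific assembler written for these data. It used 25-mers seen at least 3 times, ignored branches under 5% of the leading path and kept contigs of at least 100 nt. This gave 32914 contigs with a total length of 6992769 nt, an N50 of 220 nt and a longest contig of 14370 nt. A contig is a fragment of a transcript, and several contigs can come from 1 transcript. Contigs are numbered c1 upward and are the items of every comparison. Counts of contigs are therefore not counts of genes. Reads were aligned to the contigs with bwa mem 0.7.19-r1273 (seed length 19, minimum score 25), and only alignments on the RNA strand with the best score were kept. A read with 1 best contig counted as unique. Mapped reads were 96.8% of the mock, 93.8% of the untreated Piwi RIP and 97.4% of the ActD Piwi RIP.

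Contigs c1 and c2 each held at least 10% of the pooled unique reads and are called dominant. CPM was computed over the unique reads outside the 2 dominant contigs. A contig was tested in a comparison when it had at least 50 unique reads summed over both libraries. It was called at least 2-fold higher (or lower) when the ratio of CPM reached 2 (or its inverse) and the exact 95% Clopper-Pearson interval on the split of the 2 counts lay on that side of 1. With 1 library per group there is no replicate check and no p-value, and the calls compare libraries, not conditions. Intervals cover counting error only, because reads without molecular identifiers are not independent molecules. A ratio against a count of 0 is computed against a floor of 3 reads, and its bound is that of the counting interval. Ranges over the alternatives, given for named contigs, cover 3 other scalings (TMM, size factors and all unique reads), each distinct sequence counted once, multi-mapped reads shared, and the other aligner. A contig has a limited number of read positions, so counting distinct sequences can shrink the folds of abundant contigs without any amplification.

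The contigs named in the text follow the rule fixed for genes before the data were examined, applied to contigs. It takes contigs with at least 100 reads over both libraries and at least 20 distinct sequences in the higher library, then the 10 with the largest lower bound and the 10 with the smallest upper bound of the ratio. The parts of that rule that need gene names were not applied. Other contigs named in the text were chosen after their values were seen. The gene lists fixed before the data were examined could not be applied without gene names. In their place, contigs were grouped by short protein motifs in their longest stop-free frame on the RNA strand. The motifs were chosen after the translations had been read. A group of at least 5 contigs was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched on reads.

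A splice border was a branch of the pooled reads where 1 path began with GTAAG or GTGAG, the common start of an intron, and the other path, with more reads, did not. Reads on the first path were counted as unspliced and reads on the other as spliced. The search used 20-mers seen at least 2 times and paths that differed in at least 5 bases, and reads had to cover 12 bases on each side of the branch. This count was chosen after the data had been seen, because earlier searches for whole introns had given too few events and were not used. The ratio of unspliced to spliced reads was compared between libraries as a ratio of ratios with an exact conditional interval on the odds ratio. Reads were pooled over sites for it, so it can also move with which transcripts have more reads. As an alternative, the ratio of ratios was taken within each site, and its median over sites is given.

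The calls were tested on simulated data, with Poisson counts drawn from the real contigs and library sizes and 200 contigs changed per comparison. For the untreated Piwi RIP against the mock, 14310 simulated contigs were tested. Of the 50 tested contigs raised 3-fold, 49 were called, and of the 50 raised 1.5-fold, 7 were called. Of 14143 unchanged contigs, 66 were called. Both simulated libraries came from 1 pooled profile without other spread between libraries, so these rates cover counting error only. In the real comparison the SD of log2 ratios over abundant contigs was 1.32, against 0.113 from counting error. Scaling factors for alternatives came from edgeR 4.0.16 (TMM) and DESeq2 1.42.0 in R 4.3.3, used for scaling only. Alternatives fixed before the data were examined were these scaling factors, lower read minimums, each distinct sequence counted once, multi-mapped reads shared over their best contigs, a 1.5-fold threshold and another aligner, minimap2 2.31-r1302. Alternatives chosen after seeing the data were assembly with 31-mers, contigs of at least 200 nt, scaling to all unique reads, contigs of at most 60% GC, thinning of both libraries to the same number of reads, scaling without the 100 most abundant contigs outside the dominant ones, and leaving out 1 splice border or those on contigs with a frame under 100 codons.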

Results

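RNA recovered with Piwi, an Argonaute protein of the nucleus that binds small RNAs, was sequenced from untreated and actinomycin D (ActD) treated OSC cells, beside a mock precipitation without antibody. The labels state that the antibody recovered like amounts of Piwi from both cultures and none in the mock. The untreated Piwi RIP held 3146208 distinct sequences among 18054986 reads. The mock held 1970146 and the ActD Piwi RIP 1782626 when thinned to that depth. Each group had 1 library.

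Ribosomal RNA made up most of every library. The longer dominant contig, c1 (4060 nt), carries the sarcin-ricin loop of large-subunit ribosomal RNA, and c2 (2212 nt) carries a conserved core of small-subunit ribosomal RNA. Together they took 83.10% of the unique reads of the mock (exact 95% interval 83.08 to 83.11), 73.82% of the untreated Piwi RIP (73.80 to 73.84) and 85.86% of the ActD Piwi RIP (85.85 to 85.88). The loop pattern was widened by 1 base after its first form had not been found in c1. The reads left for all other contigs numbered 3087536 in the mock, 4431728 in the untreated Piwi RIP and 2598383 in the ActD Piwi RIP. They made up 16.9%, 26.2% and 14.1% of the unique reads.

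The first comparison asks which RNAs the antibody brought down beyond the beads. Outside the dominant contigs, 5069 of 14142 contigs were at least 2-fold higher in the untreated Piwi RIP than in the mock, and 576 were at least 2-fold lower. The median contig was 1.65-fold higher (log2 0.73). The 576 lower contigs took 26.2% of these reads in the mock and 7.87% in the untreated Piwi RIP. The 5069 higher contigs took 9.83% in the mock and 28.6% in the untreated Piwi RIP. With TMM factors, which centre the contigs near a log2 ratio of 0.01, 1375 contigs were at least 2-fold higher and 1759 lower, so the excess of higher contigs is stated relative to the summed reads and is not kept relative to the median contig. With each distinct sequence counted once, 1434 were higher and 485 lower.

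**Figure D1:**
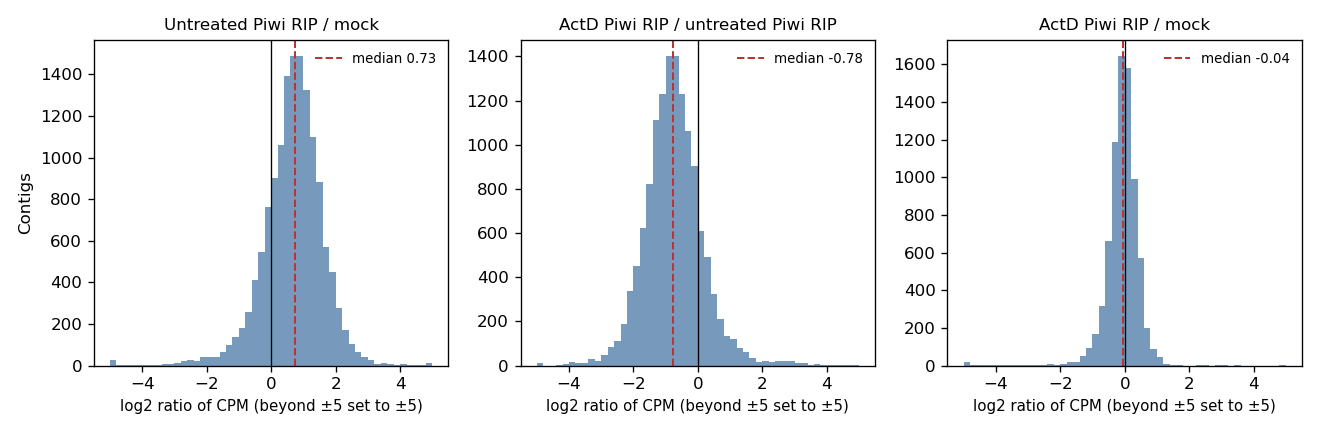
Histograms of the log2 ratio of CPM over contigs with at least 50 reads in each comparison, with the number of contigs on the vertical axis and a dashed line at the median. The median lies at 0.73 for the untreated Piwi RIP over the mock, at -0.78 for ActD over the untreated Piwi RIP and at -0.04 for ActD over the mock.

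Contigs that encode C2H2 zinc fingers, a DNA-binding fold common in transcription factors, stood above other contigs in the untreated Piwi RIP. Of 116 tested, 67 were at least 2-fold higher than in the mock, 0 were lower and 49 were not called. Their median log2 ratio was 1.15, which is 0.43 above the median of all contigs, and lay at or above the medians of all 10000 matched random lists. This position was the same, at percentile 100, when the lists were drawn only from contigs with a frame of at least 50 codons. Several of these contigs can come from 1 transcript, which the lists do not allow for. For protein kinase catalytic loops, 12 of 28 contigs were at least 2-fold higher and 0 lower (median log2 0.84, percentile 75.5). DEAD box contigs, a motif of RNA helicases, were not called in any of 7 cases (median log2 0.51, percentile 49.9), and their median is -0.22 relative to all contigs, so that the sign turns with TMM factors, which shift all contigs alike. RNP1 contigs, which mark RNA-binding proteins, had 2 of 14 higher and 0 lower (percentile 45.6), and their median of 0.60 is -0.12 relative to all contigs, with the same turn of sign.

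Retroelement motifs gave medians within the range of random lists. Contigs with a CCHC zinc knuckle, found in Gag proteins of retroelements and in some cellular proteins, had 6 of 16 members higher, 1 lower and 9 not called (median log2 0.81, percentile 80.9). Their summed share of the reads outside the dominant contigs was 3.90% in the untreated Piwi RIP and 1.49% in the mock. One member, c56 (2356 nt), had 7874 CPM in the untreated Piwi RIP and 1138 CPM in the mock, a ratio of 6.92 (counting interval 6.68 to 7.16). Over the alternatives it ranged from 2.63, with each distinct sequence counted once, to 10.7, with scaling to all unique reads. Contigs with the catalytic core of reverse transcriptases had 4 of 14 higher and 1 lower (median log2 0.39, percentile 23.3), and their median is -0.34 relative to all contigs, so that its sign turns with TMM factors. Among them c4742 was 15.2-fold higher (7.52 to 35.7; 7.80 to 23.5 over the alternatives) and c302, a contig of 169 nt with a frame of 55 codons, 104-fold lower (50.1 to 260; 31.7 to 172 over the alternatives).

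Among the 10 contigs farthest above the mock, 6 had a frame of at least 100 codons. The longest, c258 (2953 nt, frame of 318 codons), had 1982 CPM in the untreated Piwi RIP and 234 CPM in the mock, a ratio of 8.45 (7.84 to 9.13). Over the alternatives it ranged from 3.46, with each distinct sequence counted once, to 13.1, with scaling to all unique reads. Contig c2745 was 18.9-fold higher (10.4 to 38.3; 11.4 to 29.3 over the alternatives) and c2007 9.17-fold higher (6.10 to 14.4; 4.83 to 14.2). Contig c278, 122 nt long and 77.0% GC, had 468 reads in the untreated Piwi RIP and 0 in both other libraries. It was at least 88.0-fold higher than in the mock by the lower end of its counting interval, and 109-fold against a floor of 3 reads. The 10 contigs farthest below the mock were all shorter than 500 nt, and 5 had a GC content above 60%. Contig c127 (71.9% GC) had 1938 reads in the mock and 2 in the untreated Piwi RIP, a ratio of 0.000719 (8.7e-05 to 0.0026; 0.000434 to 0.00235 over the alternatives). Another, c248, carries the sarcin-ricin loop and had 596 reads in the mock, 5 in the untreated Piwi RIP and 11 in the ActD Piwi RIP. Its ratio to the mock was 0.00584, but 0.0841 with minimap2, so its level depends on the aligner. Contigs were not assigned to an organism, and short contigs of this set, c127 and c302 among them, can come from ribosomal RNA of another organism. Contigs other than c1 and c2 with a ribosomal core stretch took 0.668% of the reads outside the dominant contigs in the mock, 0.183% in the untreated Piwi RIP and 0.317% in the ActD Piwi RIP.

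**Figure D2:**
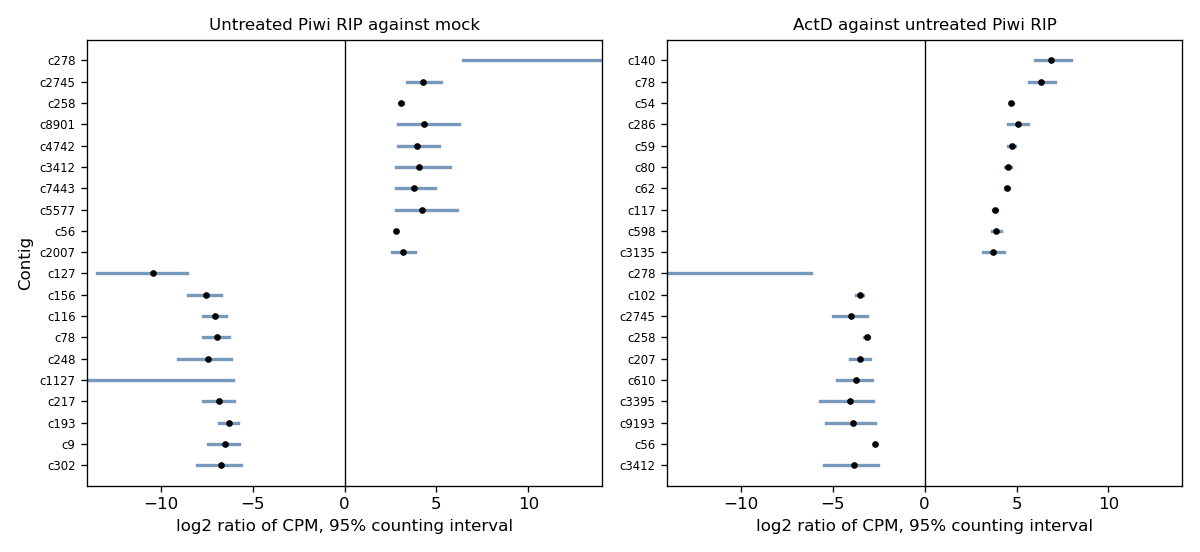
The log2 ratio of CPM (points) with its 95% counting interval (bars) for the 10 contigs farthest above and the 10 farthest below 1 in each main comparison. A bar that runs to the edge without a point marks a contig with 0 reads in 1 of the libraries, as for c278.

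The second comparison asks what blocking transcription for 1 h did to the RNA in the Piwi precipitate. Of 13351 contigs, 5118 were at least 2-fold lower in the ActD Piwi RIP than in the untreated Piwi RIP and 458 were at least 2-fold higher. The median contig was 1.72-fold lower (log2 -0.78). With TMM factors, which centre the contigs near -0.01, 1363 were lower and 1528 higher, so here too the excess of lower contigs is relative to the summed reads. With each distinct sequence counted once, 1563 were lower and 421 higher.

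The C2H2 zinc finger contigs lay below other contigs in the ActD Piwi RIP. Of 112 tested, 68 were at least 2-fold lower with ActD, 1 was higher and 43 were not called. Their median log2 ratio was -1.22, below all 10000 matched random lists and -0.44 relative to all contigs. For protein kinase loops, 12 of 28 were lower and 0 higher (median log2 -0.88, percentile 23.5). Of 16 CCHC contigs, 7 were lower and 1 higher (median log2 -0.85, percentile 19.6). Among P-loop contigs, which encode nucleotide-binding proteins, 50 of 165 were lower and 8 higher. Their median log2 ratio of -0.58 lay at percentile 95.1 of random lists and was 0.20 relative to all contigs, so that its sign turns with TMM factors. DEAD box contigs were not called in any of 7 cases, and their median log2 ratio of -0.32 is 0.46 relative to all contigs, with the same turn of sign. Both main comparisons share the untreated Piwi RIP, so the group results in them are not independent.

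Among the 10 contigs farthest below the untreated Piwi RIP, c258 was 8.90-fold lower with ActD (8.18 to 9.69), c56 was 6.50-fold lower (6.27 to 6.74) and c2745 was 15.9-fold lower (8.78 to 32.3). Over the alternatives the folds ranged from 3.55 to 16.5 for c258 and from 9.28 to 29.5 for c2745, and the ratio for c56 ranged from 0.0831 to 0.391, the last 2.56-fold lower. The smallest changes of c258 and c56 came from counting each distinct sequence once. Contig c102 (484 nt) had 73.9 CPM in the ActD Piwi RIP, against 860 CPM in the untreated Piwi RIP and 306 CPM in the mock. It was 11.6-fold lower with ActD than in the untreated Piwi RIP (10.1 to 13.5; 3.68 to 21.6 over the alternatives). In the other direction, c54 (2685 nt, frame of 847 codons) was 26.1-fold higher with ActD (24.7 to 27.5), at 8613 CPM with ActD, 331 CPM in the untreated Piwi RIP and 8565 CPM in the mock. Contigs c59, c80 and c62 were 26.4-fold, 23.2-fold and 22.3-fold higher, and with c54 they can be pieces of 1 RNA and are then 1 change and not 4. Over the alternatives the folds ranged from 9.71 to 44.7 for c54, 9.69 to 45.4 for c59, 9.98 to 39.8 for c80 and 9.28 to 38.3 for c62. The lowest of each came from counting each distinct sequence once.

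Among contigs with a splice border and a frame of at least 100 codons, the set chosen after the values were seen, c319 (2025 nt, with a kinase catalytic loop) was 5.02-fold higher in the untreated Piwi RIP than in the mock (4.64 to 5.44) and 4.70-fold lower with ActD (4.32 to 5.11). Contig c319 had 1949 distinct sequences in the untreated Piwi RIP, 504 in the mock and 463 with ActD. Its most frequent tag, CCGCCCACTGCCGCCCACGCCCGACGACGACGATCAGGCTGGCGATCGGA, had 46 reads in the untreated Piwi RIP, 9 in the mock and 3 with ActD. Contig c270 (2103 nt, frame of 701 codons) was 4.21-fold higher than in the mock (3.91 to 4.54) and 4.05-fold lower with ActD (3.74 to 4.39). Contig c270 had 1634 distinct sequences in the untreated Piwi RIP, 520 in the mock and 475 with ActD. Its tag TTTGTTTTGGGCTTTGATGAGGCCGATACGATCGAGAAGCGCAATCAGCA had 53, 10 and 7 reads in the same order. On the other side, c290 (1282 nt) was 3.45-fold lower than in the mock (3.19 to 3.73) and 3.21-fold higher with ActD (2.96 to 3.48). Its tag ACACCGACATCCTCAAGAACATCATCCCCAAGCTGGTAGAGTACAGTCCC had 14 reads in the untreated Piwi RIP, 29 in the mock and 24 with ActD. Contig c216 (5414 nt, frame of 1763 codons) was 2.04-fold lower than in the mock (1.97 to 2.11). Ranges over the alternatives were not computed for the contigs of this set. For c319 and c270 the distinct sequences differed by smaller folds than the reads.

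The third comparison set the ActD Piwi RIP against the mock. Of 7741 contigs, 76 were at least 2-fold higher, 251 were at least 2-fold lower and 7414 were not called. The median log2 ratio was -0.04. Of the C2H2 zinc finger contigs, 1 of 59 was higher and 0 lower (median log2 0.02, percentile 85.2), and of 15 CCHC contigs none was called (median log2 -0.01). Contigs without a frame of 50 codons held 145 of the lower calls among 1029 tested (median log2 -0.29), and contigs with a frame of at least 100 codons held 9 among 3573. A short contig cannot hold a long frame, so these classes also part contigs by length, and they do not part coding from noncoding RNA. Among the 6377 contigs of at least 200 nt, 99 were lower and 41 higher. This comparison shares a library with each of the others, so it adds no independent measurement.

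Reads of unspliced form were counted at 453 splice borders, which were called from sequence alone and not checked against a genome. Of these, 319 were found on a contig. On contigs with a frame of at least 100 codons lay 148, and the others can include branches that are not splice sites. The spliced path had to have more reads, so borders of mostly unspliced RNA were left out by the definition. Paths that began with GTAAG were found at 238 branch sites and GTGAG at 215, while the next most frequent start had 133 sites and the median start had 15. Unspliced reads were 493 of the 4714 reads at these borders in the mock, which is 10.5% (exact 95% interval 9.60 to 11.4), 10.5% in the untreated Piwi RIP (9.81 to 11.1) and 9.82% in the ActD Piwi RIP (8.86 to 10.8). The unspliced to spliced ratio was 1.00 times that of the mock in the untreated Piwi RIP (0.889 to 1.13), and with ActD 0.932 times that of the untreated Piwi RIP (0.815 to 1.06). Both intervals include 1, as they did over the 148 sites on contigs with a frame of at least 100 codons (0.886, 0.738 to 1.07, and 0.929, 0.751 to 1.14). The ratio to the mock depended on the choice of sites and on pooling, so no direction is given for it. The site with the most reads lay on c7, a contig with a frame of 67 codons that can be ribosomal RNA and not a spliced transcript. Without that site the ratio to the mock was 0.810 (0.718 to 0.914). Over the 56 sites with at least 50 reads it was 1.51 (1.19 to 1.92), or 1.10 (0.867 to 1.40) when that site was left out of them. The ratio of ActD to the untreated Piwi RIP over those 56 sites was 0.660 (0.503 to 0.859), and 0.807 (0.614 to 1.05), an interval that includes 1, without the site on c7. Over all sites but that one it was 1.06 (0.930 to 1.21). These values pool reads over sites. Medians of the ratio within a site used sites with at least 50 reads and reads of both forms in both libraries. The median was 0.703 over 35 sites for the untreated Piwi RIP over the mock. For ActD over the untreated Piwi RIP it was 1.34 over 30 sites. Both lie on the other side of 1 from the pooled values of the 56 sites, so no direction is given for either ratio. Antisense reads at the borders numbered 2 in the mock, 3 in the untreated Piwi RIP and 1 with ActD.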

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

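The bounds of the tests in this part were written before their results were seen, but the test that leaves out the 100 most abundant contigs was chosen after the TMM counts had been seen. The bound against the same RNA sequenced under both names was later set aside. Reads outside the comparisons were a larger share of all reads in the untreated Piwi RIP than in the mock, in 2 counts that overlap. Reads that aligned to no contig on the RNA strand made up 6.24% of all reads in the untreated Piwi RIP, 3.23% in the mock and 2.62% in the ActD Piwi RIP. Reads that aligned only to the reverse strand of a contig are part of the first count. They made up 0.0971%, 0.0609% and 0.0414%, in the same order, with the strand taken from the data and not from the labels. Both shares are of all reads, and a smaller share of ribosomal reads in the untreated Piwi RIP can raise them. The reverse-strand reads numbered 17537 beside 4431728 reads outside the dominant contigs in the untreated Piwi RIP. They numbered 11507 beside 3087536 in the mock and 7808 beside 2598383 in the ActD Piwi RIP. Antisense RNA abundant enough to assemble has contigs of its own and is not in the second share.

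The 5069 contigs at least 2-fold higher in the untreated Piwi RIP than in the mock were weighed against technical explanations. Depth outside the dominant contigs was not decided by its test, because ratios of CPM already allow for depth and thinning mainly takes contigs below 50 reads. Thinning both libraries to the same number of reads gave 3881 higher contigs, 76.6% of the count, past the bound of 75%. Of these, 3606 (71.1% of the original calls) were among the original ones. The contigs tested fell from 14142 to 11157, and 553 were lower, so an excess of higher contigs was also seen at equal depth. A trend with GC content was not decided by its test. The lowest median log2 ratio among 5 GC classes was 0.53, past its bound, but every class carries the shift of all contigs (0.73), which depends on the scaling. Contigs were called higher in every class, with 30.2% in the class of lowest GC and 36.1% to 39.3% in the others. Reads from an organism without introns stay open, because contigs with a splice border were called higher at 83.6% of the rate of all contigs, with an interval (67.5 to 101) that spans the 75% bound set beforehand, and not every border is sure to be a splice site. A scale set by abundant contigs is a possible explanation for part of the count. With the 100 most abundant contigs taken out of the scaling totals, 48.4% of the calls (47.0 to 49.8) were left. Amplification of a few sequences stays open. With each distinct sequence counted once, 68.0% of the contigs still had a counting interval above 1. At least 2-fold higher were then 28.2% of the calls, with the minimum of 50 applied to distinct sequences. Binding of nuclear transcripts by Piwi, the biological explanation the design gives, was not tested, because 1 library per group leaves it confounded with the library.

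The ActD Piwi RIP lay nearer to the mock than to the untreated Piwi RIP. Sequencing the same RNA under both names stays open. The SD of log2 ratios over abundant contigs was 8.51 times that of counting error alone. This lay past the bound written beforehand as speaking against that explanation. The bound was set aside, because preparing 2 libraries from the same RNA adds spread as well, so this value does not decide. Of 7741 contigs, 251 were at least 2-fold lower in the ActD Piwi RIP than in the mock and 76 higher. Contig c127, 1 of the 10 contigs farthest below the mock in the untreated Piwi RIP, had 1938 reads in the mock and 16 with ActD. Of the others, c116 had 2085 and 30 reads, c193 had 1850 and 35, and c156 had 1552 and 16. Contigs c217, c9, c248, c302 and c1127 had 1018 and 8, 837 and 8, 596 and 11, 507 and 3, and 176 and 2. Contig c78 had 1547 and 849. No bound had been set for such contigs, and with 1 library per group they do not decide. A loss of bound RNA after transcription was blocked and a lower yield of that single precipitation also stay open, and no replicate was there to part them. The labels state that like amounts of Piwi were recovered from both cultures, which bears on the protein and not on the RNA recovered.

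A set of 22 contigs with at least 1000 reads was at least 4-fold lower in the untreated Piwi RIP than in both other libraries, and took 6.84% of the reads outside the dominant contigs in the mock, 1.22% in the untreated Piwi RIP and 8.35% in the ActD Piwi RIP. Contig c15, at 4.22-fold lower than in the mock and 3.16-fold with each distinct sequence counted once, carried most of these reads, and the 21 others took 2.22%, 0.123% and 2.14%. RNA of an organism without introns that differed between cultures could not be decided by splice borders, because 0 of the 22 had one where 7.87% of all contigs of that depth did, a ratio of 0% with an upper bound of 196%. No biological explanation was tested for this set.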

How the results depend on the processing

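Beyond the alternatives fixed before the data were examined, the 31-mer, 200-nt, all-read, GC, thinning, most-abundant, frame and left-out-site values were chosen after seeing the data. No paired analysis was possible because each RIP group has 1 library and no test was made. Of 84 alternative counts of contigs, 40 were within 1.5 times the reported count. Alternatives that count whole gene bodies, annotated introns, transposon insertions or gene lists were not run, for want of a genome, and bwa mem was the main aligner because spliced alignment needs one. For the untreated Piwi RIP against the mock, higher and lower contigs numbered 1375 and 1759 with TMM, 1350 and 1775 with DESeq2 size factors, 9684 and 1075 with at least 10 reads, 9686 and 1076 with no filter, 3143 and 323 among contigs of at least 200 nt, 9600 and 268 scaled to all unique reads, and 2454 and 1096 scaled without the 100 most abundant contigs. Counting distinct sequences once gave 1434 higher, and the 1.5-fold threshold gave 963 lower. For ActD against the untreated Piwi RIP, the same settings gave 1528 and 1363 (TMM), 1568 and 1322 (size factors), 884 and 9801 (10 reads), 893 and 9806 (no filter), 155 and 10655 (all unique reads), and 941 and 2304 (without the 100 most abundant). Lower contigs numbered 1563 with distinct sequences, 3184 at 200 nt and 3259 after thinning, and 748 were higher at 1.5-fold. For ActD against the mock they gave 544 and 915 (10 reads), 584 and 938 (no filter), 27 and 103 (distinct sequences), 265 and 549 (1.5-fold), 41 and 99 (200 nt), and 27 and 506 (all unique reads). Filters, thresholds and contig length change the counts by construction; for the others the cause was not tested.

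The unspliced to spliced ratio of the untreated Piwi RIP over the mock was 1.51 over sites with at least 50 reads, 0.810 without the site with the most reads, 0.886 over contigs with a frame of at least 100 codons and 0.703 as a median over 35 sites. That of ActD over the untreated Piwi RIP was 0.660 over sites with at least 50 reads, 1.06 without the site with the most reads, 1.34 as a median over 30 sites and 0.807 over the deep sites without that site. These ratios depend on which sites are used and on whether reads are pooled over sites or compared within a site. The cause was not tested. The dominant contigs took 23.5%, 14.4% and 26.4% of distinct sequences and 83.5%, 74.3% and 86.2% of reads with minimap2 in the mock, untreated and ActD libraries.

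TMM shifts all contigs alike, so a change of sign with it shows only that the median of a group lies between 0 and the median of all contigs. Median log2 ratios that changed sign with TMM were, against the mock, reverse transcriptase -0.33, DEAD box -0.21, IQ -0.20, RNP1 -0.12, P-loop -0.14, splice border -0.0887 and no frame of 50 codons -0.13, the last also with distinct sequences, at -0.0356, as did DEAD box at -0.0176. For ActD against the untreated Piwi RIP they were reverse transcriptase 0.22, DEAD box 0.44, IQ 0.36, RNP1 0.24, P-loop 0.18, splice border 0.0528, frame of at least 100 codons 0.0084 and no frame of 50 codons 0.00837, and with distinct sequences reverse transcriptase 0.0234, DEAD box 0.107 and IQ 0.0485. For ActD against the mock, where these medians lay near 0, CCHC was 0.0226 with TMM, CCHC 0.0583, reverse transcriptase 0.00364, kinase 0.0412 and RNP1 -0.0277 with distinct sequences, and kinase 0.0562 with at least 10 reads. Of 234 alternative ratios of named contigs, with none for c278 over the mock because of its 0 reads there, 152 stayed within the counting interval, 82 lay outside it and none changed direction.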

Other observations

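Reads were also summed by frame length, with no test between libraries. Contigs with a frame of at least 100 codons took 62.5% of the reads outside the dominant contigs in the mock, 65.7% in the untreated Piwi RIP and 71.1% in the ActD Piwi RIP. Contigs with no frame of 50 codons took 14.5%, 13.5% and 11.1%. Frame length is limited by contig length, so these shares are not shares of coding and noncoding RNA.

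Among P-loop contigs, 50 of 164 were at least 2-fold higher in the untreated Piwi RIP than in the mock and 6 lower, with a median log2 ratio of 0.58. That median is -0.14 relative to all contigs and lay at percentile 15.8 of random lists. Among all contigs tested, 35.8% were called higher and 4.07% lower. The summed share of the group was lower in the untreated Piwi RIP than in the mock. P-loop contigs took 16.3% of the reads outside the dominant contigs in the mock, 12.7% in the untreated Piwi RIP and 19.3% in the ActD Piwi RIP. IQ motif contigs, a calmodulin-binding motif of myosins and other proteins, had 4 of 15 members at least 2-fold higher with ActD than in the untreated Piwi RIP and 3 lower.

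Within the set of contigs low in the untreated Piwi RIP, c54, c59, c62 and c80 were 25.9-fold, 28.5-fold, 23.9-fold and 22.3-fold lower than in the mock, and can be pieces of 1 RNA, in which case they are 1 change and not 4. With each distinct sequence counted once they were 9.48-fold, 9.88-fold, 9.44-fold and 9.33-fold lower. Contigs c117 and c598 were 9.54-fold and 10.3-fold lower than in the mock, or 5.39-fold and 6.91-fold with distinct sequences. Contig c15 (6319 nt, frame of 2026 codons) had 46180 CPM in the mock, 10955 CPM in the untreated Piwi RIP and 62065 CPM in the ActD Piwi RIP.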
